A study of Mus musculus with 6 samples.

How the data were processed

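RNA was measured in 6 libraries of day 7 neurosphere lysates, 3 from precipitates with anti-Cpeb4 and 3 from precipitates with control IgG. Per the labels' protocols, RNA was isolated with a Magna RIP kit, cDNA was made with the SMART-Seq v4 low-input kit and libraries with Nextera XT, which amplify by PCR, do not mark strand and carry no molecular identifiers. Per the submitters' processing notes, the tools were FastQC 0.11.5, Trim Galore 0.5.0, STAR 2.6.0c, HTSeq 0.6.1p2, DESeq and DESeq2 1.26.0, with genome build mm10; their roles, settings and the gene annotation are not given in the sources used here.

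The deposited table lists 26672 genes with an FPKM value (fragments scaled by gene-model length and library size) per library, and the authors' DESeq2 columns, per the file headers: a mean of normalized counts (a signal, the same for all libraries), the log2 fold change of Cpeb4 over IgG with its standard error, a linear fold, a test score, a p-value and an adjusted p. The model behind these deposited columns is not given in the sources used here, and the authors' mean is not the mean of these 6 libraries for every gene: among 12477 genes with a mean above 100 the ratio of the recovered to the deposited mean had a median of 0.992 and a 5th to 95th percentile of 0.837 to 1.11, and the mean deposited for Esr1 was 30.1 times the recovered one. Values from those columns are named as the authors' wherever printed. Columns name the antibody and a number; each was assigned to its antibody group and not to a sample, because the read-file names in the labels number the experiments differently from the sample titles.

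Within a gene the FPKM of the 6 libraries were whole multiples of a common step once the libraries' relative depth was solved from low genes. Whole reads were recovered for all 26672 genes (100%) at a relative tolerance of 1e-09, taking the smallest whole numbers for each gene. On 499 simulated genes, with the true relative depths supplied, the procedure returned all 499 up to a common divisor. Under a wrong scale 45 of 491 genes still gave whole numbers. The simulation does not test the recovered depths or totals. The recovered totals were 37188631, 79376507 and 72020024 reads for anti-Cpeb4 and 25150029, 67974131 and 81584130 for IgG. The FPKM denominators followed median-of-ratios size factors (ratio to their mean 0.988 to 1.01) and not read totals (0.824 to 1.26). Genes listed at 0 numbered 2659, 5032 and 4963 in the anti-Cpeb4 and 96, 2816 and 722 in the IgG libraries; a count of 0 allows up to 3 reads of the library total, a limit that covers counting error only, since reads without molecular identifiers are not independent molecules. No pair of libraries held identical values.

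Differences were tested with limma 3.58.1 in R 4.3.3 (statmod 1.5.0), with trended and robust variance, on log2(FPKM + 1), for the 12220 genes with an FPKM of at least 1 in at least 3 of 6 libraries; 14452 listed genes were not tested. Tests were two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. A log2 difference on this scale understates the change of low genes. A count model was not used because the deposited unit is FPKM. The design fixed before the data were examined had the antibody as its only term, with the experiment number as a block as an alternative. Whether numbers pair the libraries was decided from the correlation of deviations from the group means before calls were compared: it was 0.823, 0.641 and 0.655 between libraries of the same number, each library correlated best with its own number, and the highest correlation with another library was 0.451. The labels number the experiments in the same way for both antibodies. Same-numbered columns were therefore taken as pairs, and values of the paired fit are given beside the result without pairing. On data simulated from the paired fit over 12220 genes, the paired fit recovered 88 of 100 genes changed by a log2 of 1 and 100 of 100 changed by 2, with 33 false calls, and the fit without the block recovered 0 of 100 and 0 of 100. The false calls were a larger share of the calls than the threshold of 0.05 allows for. The simulated data kept the differences between pairs, so the result without the block does not bear on whether the libraries are paired.

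Gene lists, 29 in number, were written before the data were examined. They covered CPEB partners and targets, P-bodies, neural and non-neural cell types, cilia, the cell cycle, Notch, BMP and TGF-beta, Wnt and receptor tyrosine kinase signalling, immediate early genes, chromatin regulators with autism-risk genes, zinc-finger genes, ribosomal proteins, mitochondrial transcripts, oxidative phosphorylation, histones, glycolysis, cholesterol synthesis, the unfolded protein response, the clock and noncoding RNA. Lists with 5 or more tested members were tested with camera at a correlation of 0.01, adjusted over the lists, with an estimated correlation and fry beside it. Named genes followed a rule fixed at the same time: the Cpeb family and Eif4enif1; in each direction the 10 largest differences at or above the median expression and the 5 smallest adjusted p-values among genes past 0.05 and of 1 direction in all 3 pairs, passing over unnamed genes; where no gene passed, the 5 smallest p-values; and up to 4 members of each list. Since no gene passed without pairing, the rule was applied to the paired fit as well. Other list members named in the text, and the counts of 5 or fewer they complete, were chosen after their values were seen. Of the 26672 gene identifiers 24449 were found in the name table used, and coordinates of 100 of the 106 genes named by the rule come from RefSeq's annotation of the same build; symbols given to more than 1 identifier (21) were represented by the row of highest mean.

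Alternatives were median centring, quantile normalization, read-total scaling, other filters, a pseudocount of 0.1, no variance trend, a test against a fold of 1.5, voom on the recovered reads, removal of each library's trend on gene-model length (loess, span 0.3), subtraction of receptor-gene background, leaving out gene classes, and leaving out each library or pair. The planned test of polyadenylation elements in 3′ untranslated regions was not run, because no transcript sequence was used here. Figures were drawn with matplotlib 3.10.9, and reads were recovered with numpy 2.4.6 and pandas 2.3.3 in Python 3.11.15.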

Results

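Messenger RNA bound by Cpeb4 was sampled from mouse neural precursor cells by RNA immunoprecipitation, in which an antibody pulls a protein out of a cell lysate together with the RNA attached to it. Cpeb4 belongs to the cytoplasmic polyadenylation element-binding family, proteins that bind U-rich elements in the 3′ untranslated regions of mRNAs and regulate their poly(A) tails and translation. The cells were wild-type precursors of the ventricular-subventricular zone, the germinal layer along the lateral ventricles, grown for 7 days as neurospheres, which are floating clusters of dividing neural stem and progenitor cells. In each of 3 experiments, lysate was precipitated with anti-Cpeb4 and with control IgG, giving 3 libraries of each kind. The counts recovered from the FPKM came to 37188631, 79376507 and 72020024 gene-assigned reads for anti-Cpeb4. For IgG they came to 25150029, 67974131 and 81584130, each in the order of the column numbers. No input RNA was analysed here, so each difference is between 2 precipitates and not against the RNA content of the cells. The labels number the experiments without saying that they came from separate animals or cultures, so the p-values measure the spread between these precipitates, which may be technical.

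The series concerns 4E-T, a protein of P-bodies, the cytoplasmic granules in which untranslated mRNA collects. The comparison asks which transcripts were more abundant, relative to the other genes, in the anti-Cpeb4 than in the IgG precipitates. FPKM are scaled within each library, so the amount of RNA that each antibody recovered was not measured. A gene lower with anti-Cpeb4 is thus lower in relative terms and not necessarily in the amount recovered. With the experiments treated as pairs, 1181 genes were higher and 388 lower with anti-Cpeb4 among 12220 tested (limma, Benjamini-Hochberg adjusted p under 0.05). Among named genes at or above the median expression, the largest positive differences were in Smim15, Rpe and Znrd1, and the largest negative ones in Cacfd1, Lhfpl4 and the mitochondrial-genome transcript mt-Nd6. At a fold of 2 or more, on the log2(FPKM + 1) scale, 469 genes were higher and 142 lower. Among all genes tested, called or not, 54.0% differed in the same direction in all 3 pairs. Independent signs balanced around 0 would give 25%. The median difference was above 0 in each pair (0.24, 0.114 and 0.135), and such a shared shift alone raises the share. The 54.0% is therefore not a measure of reproducible recovery. Without the pairing no gene passed with limma, the smallest adjusted p was 0.305, and 862 genes were higher and 311 lower at an unadjusted p under 0.05; limma's voom on recovered reads without pairing also called 0 genes. Leaving out pair 2 reduced the paired counts to 112 higher and 88 lower, against 849 and 493 without pair 1 and 828 and 240 without pair 3. Calls were then few among all 12220 genes, so 0 calls in a gene list without pair 2 does not single that list out.

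The balance of higher against lower calls depended on how libraries were scaled. The median log2 difference of all genes tested was 0.17 with the FPKM as deposited, and 75.3% of the paired calls were higher. After centring each library on its median, 1151 genes were higher and 1100 lower, so that 51.1% were higher; 950 of the higher and 383 of the lower genes were shared with the uncentred fit. Rescaling to the recovered read totals moved the median difference to -0.15 and gave 523 higher and 1901 lower genes. The median prior degrees of freedom of the variance were 9.35 with the FPKM as deposited and infinite under the other scalings, where genes of similar expression share a single variance; the share of this in the change of the counts was not tested. The 1181 higher and the 388 lower genes all kept the sign of their difference under median centring, quantile normalization and read-total scaling. In the authors' deposited table, 3307 genes were higher and 4610 lower at an adjusted p under 0.05; 3551 of those lower genes fell below the expression filter used here. Of the paired calls, 1174 of the higher and 376 of the lower genes were called in the same direction in the authors' deposited table.

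Among named genes at or above the median expression, the largest increases with anti-Cpeb4 were in Smim15, a small membrane protein gene on chromosome 13 (108044474 to 108049146, mm10), and Rpe, which encodes ribulose-phosphate epimerase of the pentose phosphate pathway (chromosome 1, 66700797 to 66719805). Smim15 stood at 142 ± 123 FPKM (SD, n = 3) with anti-Cpeb4 and 19.1 ± 5.43 with IgG, a log2 difference of 2.53 (SE 0.38, paired adjusted p = 0.00675). Its differences within pairs were 3.96, 1.98 and 1.65, so that pair 1 lay farthest from 0. Rpe stood at 87.4 ± 50.9 against 15.9 ± 1.93 FPKM, a log2 difference of 2.25 (SE 0.31, adjusted p = 0.00538). Further increases were in Znrd1, a subunit of RNA polymerase I (log2 difference 2.08, adjusted p = 0.00275), Polr2d, a subunit of RNA polymerase II (1.93, adjusted p = 0.00314), and Gtf2h3, a subunit of the general factor TFIIH (1.96, adjusted p = 0.00344). Tsen15, a subunit of the tRNA splicing endonuclease, was at 32.5 ± 1.07 against 7.77 ± 2.09 FPKM (1.96). Chac2, a glutathione-degrading enzyme, differed by 1.99, Coa6, an assembly factor of cytochrome c oxidase, by 1.97, Cldnd1 by 1.91, the endoplasmic reticulum prolyl isomerase Ppib by 1.89 and Rgcc, a regulator of the cell cycle, by 1.89, with paired adjusted p-values between 0.00314 and 0.00595. Ttc32 (1.82) and Anapc10 (1.81), a subunit of the anaphase-promoting complex, were among the genes with the smallest p-values without pairing, where both had an adjusted p of 0.305.

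**Figure D1:**
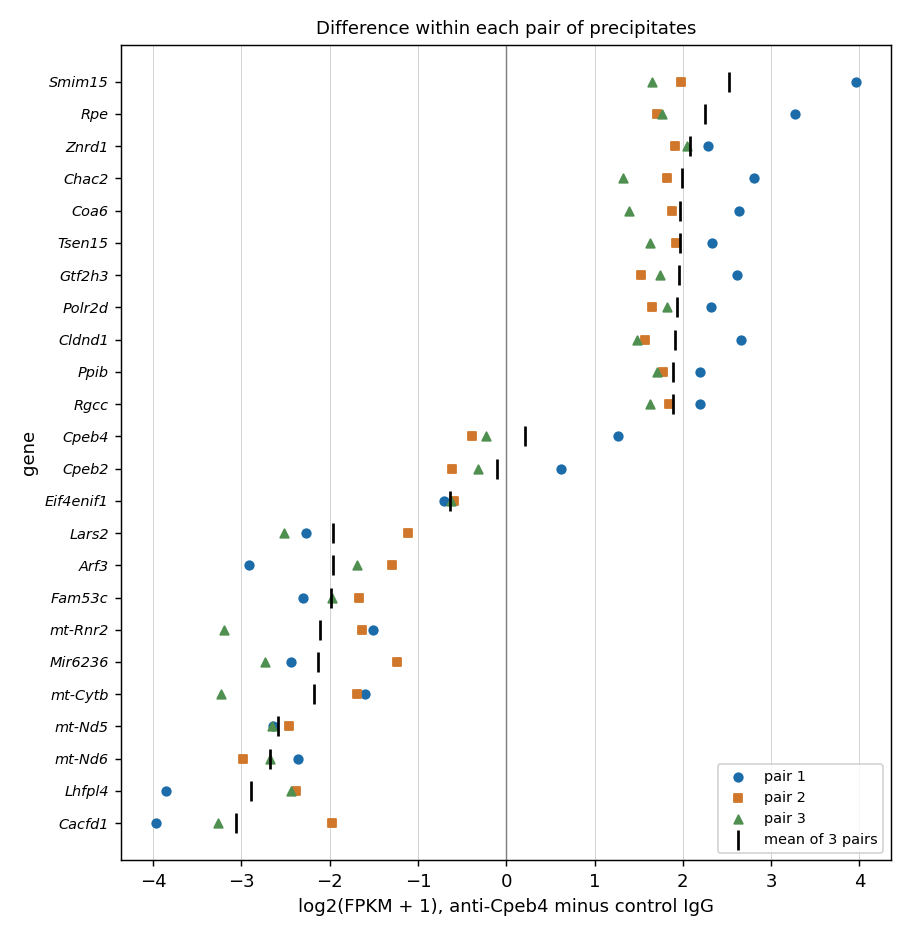
Differences in log2(FPKM + 1), anti-Cpeb4 minus control IgG, for the genes named by size or p-value in the paired fit and for Cpeb4, Cpeb2 and Eif4enif1; points are the 3 pairs and the vertical tick is their mean. Genes chosen by size or p-value had to lie on the same side of 0 in all 3 pairs to be shown. Cpeb4, shown whatever its value, is at 1.27 in pair 1 and at -0.39 and -0.23 in the other pairs.

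Among named genes at or above the median expression, the largest decreases were in Cacfd1 (chromosome 2, 27009855 to 27021090, mm10), at 19.8 ± 8.82 FPKM with anti-Cpeb4 and 171 ± 60.3 with IgG (log2 difference -3.07, SE 0.33, paired adjusted p = 0.0034), and Lhfpl4, a partner of inhibitory synaptic receptors (chromosome 6, 113168087 to 113195384), at 4.18 ± 1.29 against 38.9 ± 16.4 FPKM (-2.90, SE 0.30, adjusted p = 0.00314). Mitochondrial-genome transcripts followed, with mt-Nd6 at -2.67, mt-Nd5 at -2.59, mt-Cytb at -2.17 and the large ribosomal RNA mt-Rnr2 at -2.11. The lower genes also included Fam53c (-1.98, adjusted p = 0.00314), the small GTPase gene Arf3 (-1.97), Lars2, the mitochondrial leucyl-tRNA synthetase (-1.97), Fam160b2 (-1.99), Tbc1d22b (-1.65) and the microRNA gene model Mir6236 (-2.14). Mitochondrial transcripts have nuclear copies, and short gene models such as Mir6236 can share reads with repeated sequence. Their values are therefore uncertain where the authors' counting could split such reads. In pairs 1, 2 and 3 Lars2 differed by -2.27, -1.11 and -2.52, near the -2.44, -1.23 and -2.73 of Mir6236. Whether Lars2 also takes up reads of repeated sequence was not tested. The libraries were not stranded, so reads of mt-Nd6 cannot be told from antisense reads of the opposite strand.

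Of the transcripts of the Cpeb family, Cpeb4 and Cpeb2 were tested and not called. Cpeb4 (chromosome 11, 31870104 to 31935635, mm10) stood at 11.0 ± 13.0 FPKM with anti-Cpeb4 and 6.44 ± 3.25 with IgG, a log2 difference of 0.22 (SE 0.31, paired adjusted p = 0.663), and was higher in 1 of 3 pairs. Its sign turned to -0.31 without pair 1 and to -0.12 with read-total scaling. Cpeb2 differed by -0.11 (SE 0.25, adjusted p = 0.795) and turned to 0.15 without pair 2. Cpeb1, at 1.26 ± 0.706 against 1.33 ± 1.0 FPKM, and Cpeb3, at 0.850 ± 0.417 against 0.810 ± 0.177, did not reach the expression filter in 3 libraries. Eif4enif1, the gene of 4E-T (chromosome 11, 3202343 to 3244588), had 17.0 ± 1.63 FPKM with anti-Cpeb4 and 27.0 ± 1.64 with IgG; its log2 difference of -0.64 (SE 0.21) had the same sign in all 3 pairs and a paired adjusted p of 0.0629, which did not pass here. After median centring its difference relative to the other genes was -0.80 with an adjusted p of 0.00957. With each library's trend on gene-model length removed it was -0.70 (paired adjusted p = 0.0435). The authors' deposited table gives -0.67 with an adjusted p of 1.37e-06.

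Of the 29 gene lists fixed for the comparison, 26 had at least 5 tested members and were tested with limma's camera at a preset correlation of 0.01. Cholesterol synthesis was the only list higher than the other genes without pairing, with an adjusted p of 0.0365, which became 0.157 without pair 3 and 1 with an estimated correlation. Of its 24 tested genes, 8 were higher and 0 lower in the paired fit (7 and 0 after median centring), also 8 when adjusted over the list alone, among them Idi1, isopentenyl diphosphate isomerase (1.58, SE 0.31), Msmo1 (1.26, SE 0.23), Hmgcs1, the cytosolic HMG-CoA synthase (1.13, SE 0.25), and Ebp (0.86, SE 0.21). The list's median log2 difference was 0.38 with the FPKM as deposited, 0.22 after median centring, -0.01 after quantile normalization and 0.00 with read-total scaling. Without pair 2, 1 of its genes was called higher.

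Glycolytic genes passed by camera with pairing, at an adjusted p of 0.00719 that became 0.852 with an estimated correlation. Over all 6 libraries without pairing the adjusted p by camera was 0.0686. It was 0.00502 when pair 1 was left out, 0.0886 without pair 2 and 0.547 without pair 3. Of 23 tested, 5 were higher and 0 lower (3 and 0 after median centring), and 14 were higher when adjusted over the list alone. Eno1 (0.92), Ldha (0.84), Pgk1 (0.78) and the lactate transporter gene Slc16a1 (0.90) were higher, with paired adjusted p-values between 0.0219 and 0.0394; the fifth, Aldoc (0.75), also belongs to the astrocyte list. With the length trend removed, Eno1 (0.0547), Pgk1 (0.0659) and Aldoc (0.0591) lost their calls. Their log2 differences then stood at 0.78, 0.65 and 0.65. The list median was above 0 under all 4 scalings, between 0.12 and 0.58. Without pair 1 or without pair 2, 0 of its genes were called, and without pair 3, 2.

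Transcripts encoded by the mitochondrial genome were lower as a group, with an adjusted p by camera of 3.67e-05 without pairing and 0.846 with an estimated correlation. Of the 9 tested, 8 were lower in the paired fit, and all 9 when adjusted over the list alone, with a median log2 difference of -1.48 and a negative median under each scaling. mt-Nd5 and mt-Nd6, subunits of respiratory complex I, had paired adjusted p-values of 0.000452; mt-Nd4 was at -1.48 (SE 0.25). Without pair 2, 5 of the genes were called. Reads of all mitochondrial-genome genes made up 0.420%, 0.0868% and 0.0247% of the reads of the anti-Cpeb4 libraries and 1.35%, 0.237% and 0.163% of the IgG libraries numbered 1, 2 and 3. Nuclear genes of oxidative phosphorylation depended on the scaling. Of 80 tested, 12 were higher with the FPKM as deposited, including cytochrome c (Cycs, 1.41), Uqcrc2 (1.11), Uqcrfs1 (0.99) and Sdhd (0.98), and 1, Cox8a, was lower (-0.76; call lost with the length trend removed, 0.0512); adjusted over the list alone, 15 were higher and 2 lower. After median centring 6 were higher and 5 lower, and the list median of 0.11 became -0.06, or -0.29 with quantile normalization and -0.27 with read-total scaling. That list's set test did not pass (adjusted p = 0.769), and it passed as lower without pair 2 (0.0291). In the paired fit without pair 2, 0 of its genes were called. Without pair 1, 4 were higher and 1 lower, and without pair 3, 7 and 0.

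Nuclear-retained and long noncoding RNAs were also lower by camera, with an adjusted p of 1.45e-04, or 0.846 with an estimated correlation. Of 10 tested, 4 were lower and 0 higher (7 and 0 after median centring), and 5 were lower when adjusted over the list alone. They were the imprinted H19 (-2.14, SE 0.42), the nuclear-speckle RNA Malat1 (-1.24, SE 0.34), the X-linked Firre (-0.74, SE 0.19) and Peg13 (-0.71, SE 0.21). Malat1 (chromosome 19, 5795690 to 5802672, mm10) differed by -0.08 in pair 1 and by -1.50 and -2.12 in pairs 2 and 3; with the trend on gene-model length removed it was at -1.07 and lost its call (paired adjusted p = 0.0664). Without pair 2, 1 of these genes was called.

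Chromatin regulators and autism-risk genes, long transcripts for the most part, were lower as a list by camera, with an adjusted p of 4.11e-09, or 0.846 with an estimated correlation. Of 44 tested, 8 were lower and 0 higher in the paired fit, and adjusted over the list alone 10 were lower and 1 higher. The histone methyltransferase genes Kmt2d (chromosome 15, 98831669 to 98874077, mm10; log2 difference -1.24, SE 0.21, paired adjusted p = 0.00779) and Kmt2a (-0.78), the acetyltransferase gene Crebbp (-1.0) and the synaptic adhesion gene Nlgn3 (-0.91) were the named members, and Arid1a, Chd2, Ash1l and Kdm6b were the others. With each library's trend on gene-model length removed, Kmt2a stood at -0.32 (paired adjusted p = 0.231) and Nlgn3 at -0.66 (0.0551), and both lost their calls, as did Arid1a (0.0875), Chd2 (0.0989), Ash1l (0.129) and Kdm6b (0.0898), so that Kmt2d and Crebbp stayed called. Of the 95 genes named by the rule and called in the paired fit, 20 lost their calls in this way, all with the same direction, at adjusted p-values from 0.0547 to 0.231. After median centring, 18 of the 44 were lower and 2 higher. The members' median gene-model length was 8525 bases against 3204 for all genes tested, and in pair 2 the difference between precipitates fell with length, with a Spearman correlation across genes of -0.513, against 0.0874 in pair 1 and 0.0234 in pair 3; genes are not independent replicates. The list's median was -0.12, -0.75 and -0.08 in pairs 1, 2 and 3, and without pair 2 none of its genes was called (0 higher, 0 lower). Among all genes tested, 112 were then higher and 88 lower.

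**Figure D2:**
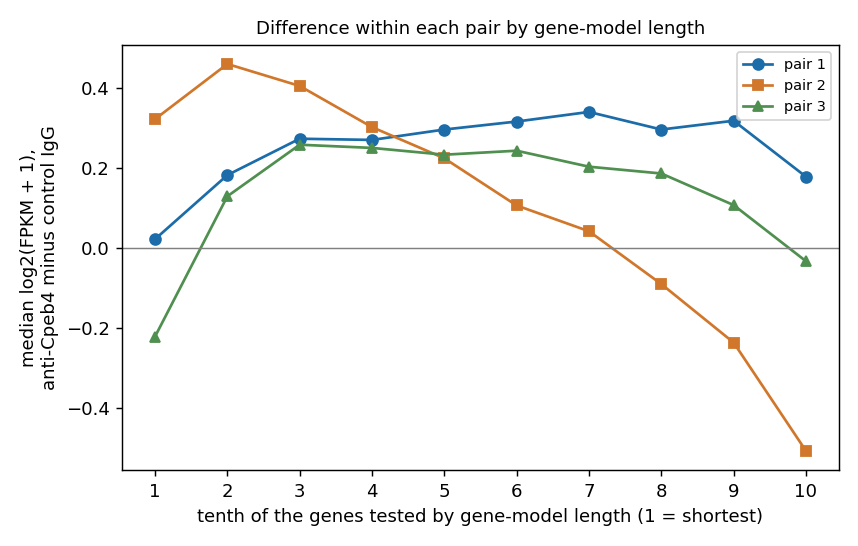
Median difference in log2(FPKM + 1), anti-Cpeb4 minus control IgG, of the genes tested in 10 classes of gene-model length from the shortest (1) to the longest (10), for each of the 3 pairs. In pair 2 the median passes from 0.46 in class 2 to -0.51 in class 10, while pairs 1 and 3 are lowest in class 1, at 0.02 and -0.22.

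Cytosolic ribosomal protein genes and replication-dependent histones were lower than the other genes by the set test, and the number of members that passed individually depended on the scaling. Both lists had an adjusted p of 1 with an estimated correlation. Of 83 ribosomal protein genes, 2 were higher, Rps27 (1.45) and Rps4l (0.83), and 0 lower, and adjusted over the list alone 1 was higher; after median centring 2 were higher and 15 lower. These genes have many processed pseudogenes, so their values are uncertain. The list median was -0.09, with pair medians of 0.08, 0.38 and -0.77, and the set test's adjusted p of 0.0195 turned to the opposite direction at 0.751 without pair 3. Of 19 histone genes, 0 were called with the FPKM as deposited, also when adjusted over the list alone, and 10 were lower and 0 higher after median centring; Hist1h2ap (-1.04) and Hist3h2a (0.67) had the smallest p-values. Their median was -0.40 and the set test's adjusted p of 0.0171 became 0.592 without pair 3. How far the cDNA kit copies histone mRNA was not tested.

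**Figure D3:**
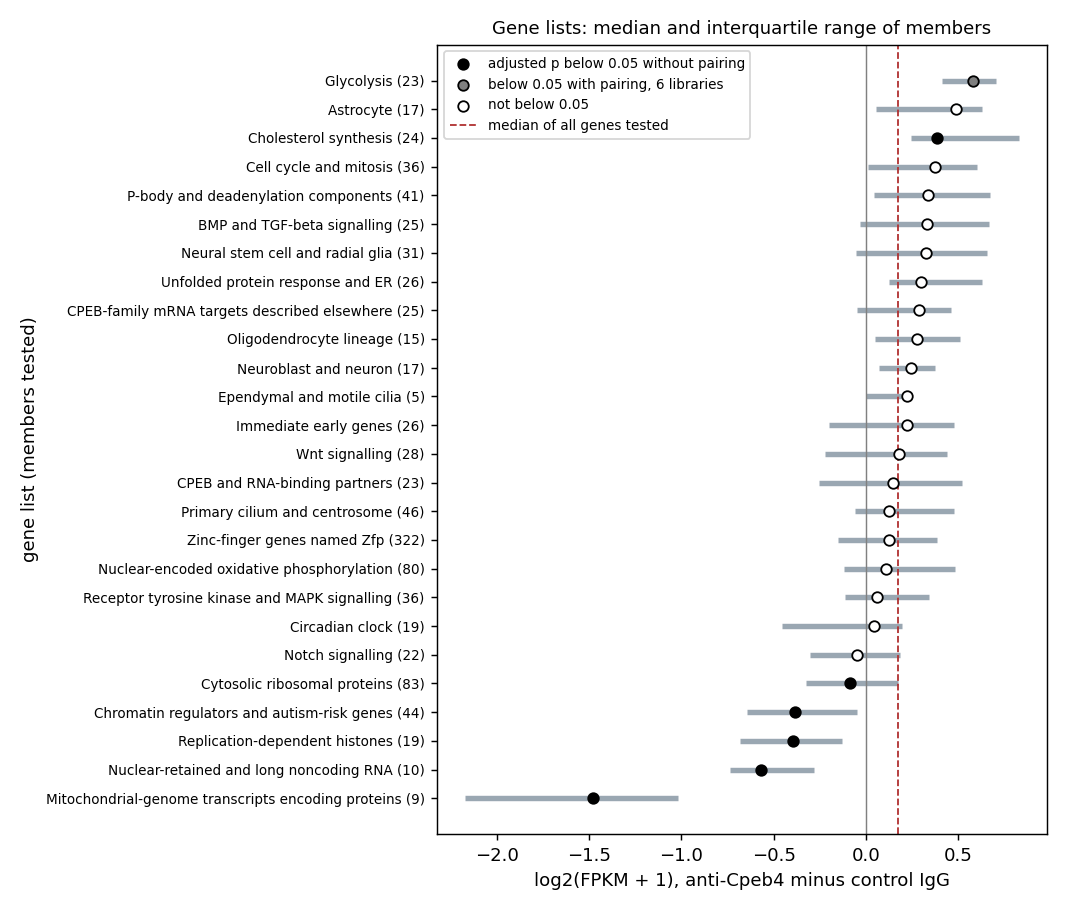
Median (point) and interquartile range (bar) of the log2(FPKM + 1) difference, anti-Cpeb4 minus control IgG, over the tested members of each of 26 gene lists, with the number of members in parentheses. Black points mark lists with an adjusted p below 0.05 by camera without pairing and the grey point the list that passed over all 6 libraries with pairing and not without it; the dashed line is the median of all genes tested, 0.17.

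The other 19 lists were not called by camera with or without pairing, with adjusted p-values of 0.103 or more; with fry, which asks whether a list's genes move one way on balance, none of the 26 lists passed in either fit; 8 of the 26 passed in the paired fit when either direction counted, 4 of them among these 19 (astrocyte, primary cilium, cell cycle and oxidative phosphorylation). Neural stem cell and radial glia genes had 7 of 31 members higher and 0 lower (4 and 2 after median centring), also 7 when adjusted over the list alone, including Hopx (1.32), glutamine synthetase (Glul, 0.97), vimentin (Vim, 0.77) and Id4 (0.79). The astrocyte list had 4 of 17 higher (7 adjusted over the list alone, 2 after median centring), namely Aqp4 (1.07), Acsbg1 (0.92), Apoe (0.78) and Aldoc (0.75). Of 15 oligodendrocyte-lineage genes 3 were higher, also 3 adjusted over the list alone: Lhfpl3 (0.99), the lineage transcription factor Olig2 (0.92) and Cnp (0.87). Of 17 neuroblast and neuron genes Elavl4 alone was higher (1.37), and 0 were called when adjusted over the list alone; after median centring 2 were higher and 1 lower. Ependymal and motile cilia genes had 0 of 5 called, with Rsph9 at 0.57 and Myb at 0.25. Primary cilium and centrosome genes had 5 of 46 higher, among them Ttc8 (1.39), Tctn2 (1.23), B9d1 (1.10) and Ift43 (0.98), and 1 lower, Cep164 (-0.67), with 5 and 1 adjusted over the list alone and 5 and 4 after median centring. In the cell cycle list, 5 of 36 were higher, including Rrm2 (1.07), Pcna (0.99) and Cdk4 (0.90), and 3 lower, E2f1 (-1.89), Mki67 (-0.94) and Ccnd2 (-0.86); adjusted over the list alone, 9 were higher and 3 lower, and E2f1 alone passed without pairing (adjusted p = 0.0223). Without pair 2, the neural stem cell, astrocyte, oligodendrocyte and neuroblast lists had 0 genes called in the paired fit. The primary cilium list then had 2 higher and 0 lower, and the cell cycle list 0 higher and 1 lower. Among the genes of this paragraph, Vim (0.0560), Apoe (0.0576), Aldoc (0.0591), Lhfpl3 (0.0752), Olig2 (0.0622), Elavl4 (0.0564), Cep164 (0.0594), Mki67 (0.0654) and Ccnd2 (0.0573) lost their calls with the length trend removed. The log2 differences of the higher genes among them then stood at 0.68 (Vim), 0.66 (Apoe), 0.65 (Aldoc), 0.90 (Lhfpl3), 0.80 (Olig2) and 1.34 (Elavl4).

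Components of P-bodies and deadenylation went both ways. Of 41 tested, 5 were higher and 3 lower, or 6 and 4 when adjusted over the list alone and 7 and 6 after median centring. In the paired fit, 1 was higher and 3 lower without pair 1, 1 and 0 without pair 2, and 4 and 1 without pair 3. Lsm3 (1.48), Lsm6 (0.89) and Lsm7 (0.88), subunits of the Lsm ring that binds the 3′ ends of deadenylated mRNA, and the deadenylase subunits Cnot8 (0.86) and Cnot10 (0.74) were higher. The 3 lower genes were the microRNA-silencing scaffolds Tnrc6a (-0.83), Tnrc6c (-0.81) and Tnrc6b (-0.77). They are long gene models, and with the length trend removed Tnrc6a stood at -0.61 (paired adjusted p = 0.0641), Tnrc6c at -0.45 (0.127) and Tnrc6b at -0.30 (0.284), none of them called; Cnot8 (0.0719) and Lsm7 (0.0550) also lost their calls. Among 23 tested CPEB and RNA-binding partners, Caprin1 was higher (0.98) and the cap-binding Eif4e2 lower (-0.96), with the same counts of 1 and 1 adjusted over the list alone and 2 and 4 after median centring. Among 25 CPEB-family targets described elsewhere, Plat, the tissue plasminogen activator gene, was higher (0.95) and the postsynaptic scaffold gene Dlg4 lower (-0.88), again 1 and 1 adjusted over the list alone, and 3 and 1 after median centring; the list's median of 0.29 lay 0.11 above that of all genes (set test adjusted p = 0.720). Without pair 2, 0 genes of the CPEB partner and CPEB target lists were called.

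Signalling lists had few calls. In the paired fit without pair 2, the lists of this paragraph had 0 genes called, apart from 1 lower gene among those named Zfp. In the BMP and TGF-beta list, Id1 (0.72), Id3 (0.71) and Id4 (0.79) were higher and the ligand gene Bmp7 lower (-1.40) among 25 tested, with 3 and 1 adjusted over the list alone. After median centring the balance turned to 1 higher, Id4, and 3 lower, Bmp7, Acvr2b and Acvr1b. In the Wnt list, Wls, which carries Wnt ligands to the cell surface (1.12), and beta-catenin (Ctnnb1, 0.94) were higher and Dvl3 (-1.06) lower among 28, with 2 and 1 adjusted over the list alone and 2 and 2 after median centring. Among 26 immediate early genes Arc was higher (0.97), with 1 adjusted over the list alone; after median centring 1 was higher and 3 lower. None of 22 Notch pathway genes was called with the FPKM as deposited (0 higher, 0 lower), with Notch3 at -0.71 and Hey1 at 0.58; after median centring 3 were lower, Notch3, Lfng and Rfng. Of 26 genes of the unfolded protein response and endoplasmic reticulum, the disulfide isomerase genes Pdia6 (0.83) and Pdia3 (0.77) were higher, with 7 adjusted over the list alone; after median centring 2 were higher and 1 lower. Of 19 circadian clock genes, Cry1 (1.23) and Dbp (0.93) were higher and Csnk1e (-1.15) and Cry2 (-1.08) lower, with 3 and 2 adjusted over the list alone and 3 and 4 after median centring. Of 322 zinc-finger genes named Zfp, 10 were higher and 11 lower, among them Zfp422 (1.17), Zfp839 (-1.20), Zfp97 (-0.94) and Zfp960 (-0.88); adjusted over the list alone, 0 were higher and 3 lower, and after median centring 18 were higher and 26 lower. With the length trend removed, Id1 (0.0594), Id3 (0.0749), Ctnnb1 (0.0550), Pdia6 (0.0663), Pdia3 (0.0634) and Dbp (0.0562) lost their calls. Their log2 differences then stood at 0.63, 0.60, 0.87, 0.70, 0.67 and 0.79, in that order.

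Markers of cells outside the neural lineage were mostly below the expression filter. Of the endothelial, mural, fibroblast and choroid plexus list 3 were tested and 0 were called over all genes, with Acta2 at 0.66 and Tagln at 0.20; adjusted over the list alone, 1 was higher. Of the blood list 0 were tested. The IgG libraries held more reads over genes that stayed below the filter, 1.69%, 0.528% and 0.709% of reads against 0.702%, 0.367% and 0.410% in the anti-Cpeb4 libraries numbered 1, 2 and 3. Reads over 625 olfactory and vomeronasal receptor genes came to 0.0385%, 0.00219% and 0.00677% of reads in the IgG libraries and 0.00393%, 0.00117% and 0.00102% in the anti-Cpeb4 libraries. The libraries of pair 1 stood apart from the rest. The anti-Cpeb4 library of pair 1 correlated at 0.851 and 0.860 with the other anti-Cpeb4 libraries, across genes on the log2 scale, against 0.978 between those.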

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

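Pairing decided the gene calls. Without the replicate block 0 genes passed in either direction under each of the 10 alternatives run on all 6 libraries and under each left-out library or pair, so these say nothing about stability. With the replicate block, 1181 genes were higher and 388 lower. The combinations that follow keep the block and were, except for the block itself, chosen after seeing the data. Median centring gave 1151 and 1100, quantile normalization 995 and 1057, and read-total scaling 523 and 1901. A fit without variance trend gave 1309 and 366, no filter on low values 118 and 79, a filter at 5 FPKM 1376 and 279, a pseudocount of 0.1 1372 and 439, and a test against a fold of 1.5 gave 5 and 10. Leaving out mitochondrial-genome, ribosomal protein and unnamed genes gave 1276 and 355, voom on recovered reads 1652 and 531, removal of the length trend 888 and 394, and background subtraction 1128 and 354. Voom shared 1170 of the higher and 373 of the lower genes with the paired fit, and the length-corrected fit 777 and 275. Over fits that left out a library or a pair, with and without the block, counts ranged from 0 to 849 higher and from 0 to 493 lower; the low end is that of the fits without the block, and with it leaving out pair 2 gave 112 and 88. With the block, the counts were 849 and 493 without pair 1 and 828 and 240 without pair 3. Each left-out pair removes the same number of libraries, so that number alone does not account for the lower counts without pair 2. The cause was not tested.

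Of the gene lists, 1 was higher and 5 were lower without the block. The replicate block added glycolysis (adjusted p = 0.00719; 2 lists higher, 5 lower) and changed no other list's call; removing the length trend with the block also gave 2 and 5, with glycolysis at 0.015. With an estimated correlation 0 lists were higher and 0 lower in both fits. The chromatin, mitochondrial-genome and noncoding RNA lists then had an adjusted p of 0.846 and the ribosomal protein, histone and cholesterol lists 1; with the block it was 0.676 for the mitochondrial-genome, noncoding RNA and cholesterol lists and 0.961 for the chromatin, ribosomal protein and histone lists. Leaving out a pair gave 0 to 2 lists higher and 3 to 8 lower. Over the left-out pairs, with and without the block, adjusted p-values ranged from 0.0126 to 0.157 for cholesterol synthesis, 0.00502 to 0.547 for glycolysis, 1.13e-07 to 0.592 for histones, 0.0123 to 0.86 for oxidative phosphorylation, 0.0491 to 0.327 for Notch signalling, 0.0295 to 0.327 for the circadian clock and 0.0181 to 0.993 for zinc-finger genes. The ribosomal protein list ranged from 1.09e-09 to 0.751 and reversed without pair 3, at 0.751, or 0.654 with the block. The cause was not tested.

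Among 3670 values of 106 named genes under 35 alternatives, 3658 kept their direction and 12 reversed, all in Cpeb4 and Cpeb2, neither of them called. Of the 106 genes, 95 were called in the paired fit, and all 1569 called genes had 1 direction in all 3 pairs. Leaving out a pair could not reverse those genes, so the kept directions follow largely from how the genes were chosen and do not test stability. Cpeb4 was at 0.22 and at -0.12 after read-total scaling with or without the block, and ranged from -0.65 to 0.70 over left-out libraries and pairs. Cpeb2 was at -0.11 and ranged from -0.64 to 0.28. The cause was not tested. The planned test of polyadenylation elements and its alternatives were not run, because no transcript sequence was used here, nor were the alternatives that need counts or size-factor-scaled values as deposited. The effect of depth on the calls was not tested; below the filter, genes are listed at 0 in up to 5032 of 26672 cases in a library.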

Other observations

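The gene groups in this paragraph were chosen after the gene results were seen. Some hold genes named above, such as Lhfpl4, Znrd1, Anapc10 and Mir6236. Their set-test p-values describe the groups and cannot support them, since the same data led to the choice. The 3 tests of technical explanations and the split counts further on were written down before their results were seen. Of 35 proteasome subunits tested, 14 were higher and 0 lower in the paired fit (9 and 0 after median centring), all 35 had a positive difference, and their median log2 difference was 0.65. Psmc6 (1.75, SE 0.29), an ATPase of the base, and Psma4 (1.30, SE 0.21) and Psma3 (1.12, SE 0.23), subunits of the core, were among those called. Camera gave a paired adjusted p of 3.24e-08 for the group, and an adjusted p of 0.193 with an estimated correlation. RNA polymerase subunits had 6 of 29 higher and 0 lower (6 and 2 after median centring), among them Polr2h (1.26), and the anaphase-promoting complex 3 of 14 (2 after centring), Anapc10 (1.81), Cdc26 (1.70) and Cdc23 (0.77); their paired adjusted p-values were 0.0881 and 0.0547, those without pairing 0.131 and 0.0317, and with an estimated correlation both were 0.193. Synapse genes went the other way, with 7 of 28 lower (8 lower and 2 higher after median centring), including the release-machinery genes Cplx2 (-2.34) and Vamp2 (-1.42), and Gphn alone higher (0.88; call lost with the length trend removed, 0.0512); the paired adjusted p was 1.67e-05, and 0.193 with an estimated correlation. Gene models under 200 bases, mostly small RNA genes, had 34 of 115 lower and 3 higher, or 57 and 2 after median centring. Camera's paired adjusted p was 1.04e-16, 0.0345 after the length trend was removed, and 0.193 with an estimated correlation. How far the cDNA kit copies such short RNA was not tested, so these values may not measure precipitated small RNA.

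The lower values of chromatin regulators and autism-risk genes were set against their length. With each library's trend on gene-model length removed, the median of the list was -0.10 (-0.102), below the 95% range of 0.04 to 0.32 of 10000 random lists matched on length and expression, and its paired adjusted p was 0.00777 at the preset correlation; before the correction the paired call was lost with an estimated correlation (0.961), which was not tested after it. The random lists, which like the preset correlation take genes as nearly independent, argue against a length trend common to all genes as the whole cause, although the median before the correction was -0.38, so that the trend may account for part of it. Without pair 2, in which the trend was steepest, none of the list's genes was called (0). Among all 12220 genes tested, 112 were then higher and 88 lower, so the 0 says little about the length trend. Camera's adjusted p of 0.00405 without pair 2 was at the preset correlation only, and an estimated one was not tested there. A lower recovery of these transcripts relative to other genes, with anti-Cpeb4 than with IgG, stays open as a hypothesis. So do other properties that go with length, such as untranslated-region content, which was not tested.

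The IgG libraries held more low-level reads over genes that neural precursors do not use. The median FPKM of 625 receptor genes was higher in the IgG library in 3 of 3 pairs. It was 0.115 against 0.0091 in pair 1, 0.00223 against 0 in pair 2 and 0.0150 against 0 in pair 3. Reads from genomic DNA or other unspliced background would give such a pattern. A weaker amplification of little starting RNA could give it too and was not tested. Such background might lower many genes with anti-Cpeb4 by raising them in IgG. Subtracting each library's receptor-gene background before the log left 354 of the 388 lower genes called lower. The subtracted medians were at most 0.115 FPKM, against a filter of 1 FPKM, so the subtraction could hardly end most calls. The result covers a uniform background of that size and does not test a larger one. Background that differs between genes, such as mitochondrial or repeat-derived reads, was not removed by this subtraction and stays open for those transcripts. Reads over satellite-like gene models were also a higher share in the IgG library of each pair, for example 0.384% against 0.0230% in pair 1.

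In the fit without pairing all 10 of the 10 splits of the 6 libraries gave as many genes as the real split, which gave 0, and the highest of the others was also 0. Within pairs there are 4 assignments of the antibody, and 1, the real one, gave 1569 genes, where the highest other gave 0; 10 splits or 4 assignments are too few for a share under 0.05.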
